A study of Rattus norvegicus with 48 samples.

How the data were processed

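The series holds lung RNA sequencing of 48 rats in 6 groups of 8, air or exposed at day 1, 7 or 27 after the exposure. Groups, days and animal numbers were taken from the labels. Per the labels' protocols, RNA was extracted from a piece of lung and libraries were made with a strand-preserving kit for polyadenylated RNA. The submitters' processing notes name bcl2fastq 2.19, cutadapt 3.4, Trim Galore 0.6.7, STAR 2.6.1d and Salmon 1.10.1 and the rat build Rnor_6.0, without giving their settings. The labels say that the rats were housed in pairs but not which animals shared a cage, and give no sequencing batch.

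The deposited values are expected counts, estimates of fragments per gene that need not be whole, in 3 tables of 32285 gene identifiers with gene names, 1 table per day. They were not normalized. Of the values, 5.58% were not whole on average per library at a tolerance of 1e-06, and all were rounded to whole numbers before testing. Of the identifiers, 4671 share their gene name with another. For the gene lists and the ribosomal protein and respiratory chain sets, the identifier with the most counts stood for its name. Coordinates are not given, since the gene table used here is of another build.

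Each day was tested by itself with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment with a threshold of 0.05. SE of a log2 fold change is its size divided by the square root of F. Differences between days were contrasts in 1 fit of all 48 libraries. Gene lists, 32 in number with 448 of 470 genes having a row, were fixed before the data were examined and tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 4 measured members, and again with an estimated correlation. CPM values were computed from the rounded counts with TMM factors. List levels, library totals and ribosomal protein levels were compared with exact two-sided permutation tests. Adjusted p in the text are from edgeR or camera unless another test is named.

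Genes were named by a rule fixed before the data were examined. It took, per day, the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol, and at least 7 of 8 exposed libraries on the same side of the air mean. It also took up to 2 called members per list, 10 marker genes at every day, and the 5 genes with the smallest p per contrast between days. Genes named because they passed adjusted over a list alone, and those said to be chosen after their values were seen, fall outside it.

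The alternatives fixed before the data were examined were RLE size factors, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, all 48 libraries in one fit, 1 surrogate variable from sva 3.50.0 and the log2 total count as a covariate. Library pairs were compared over genes with a mean of at least 20 counts, as the squared difference over its counting variance. That comparison led to alternatives chosen after seeing the data, in which the closest pair was summed, averaged or reduced to 1 library, the ribosomal protein level was a covariate, or each library was left out in turn.

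The steps were tested on simulated counts with the libraries' means, sizes and spreads and 200 changed genes. Each gene was drawn independently, and no close pair was built into the tests of changed genes. Correlation between genes in the real libraries is thus not covered by the shares recovered. EdgeR called 8, 11 and 3 unchanged genes in the simulations of days 1, 7 and 27. By edgeR, 44% of genes changed 1.25-fold and 78% of those changed 1.5-fold were recovered in the day 1 simulation of 14198 genes, 58% and 78% in the day 7 simulation of 14156 genes, and 36% and 80% in the day 27 simulation of 14082 genes. A 2-fold change present at day 27 alone was recovered for 80% of genes in the contrast with day 1, in 14763 genes. A pair of libraries simulated from the same expression levels, with counting noise alone between them, came out as the closest, at 1.02 times counting noise. Totals of 9445687 to 14400337 counts limit what can be seen of genes near 1 CPM. In the main tests p-values set a difference against the spread between the libraries of a group. Each library counts there as a separate animal, and no term for cage was fitted.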

Results

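Lung RNA from 48 male Sprague-Dawley rats was measured by sequencing of polyadenylated transcripts. The animals had inhaled, by whole-body exposure, either filtered air or a mixture of 30 mg/m3 fracking sand dust, the mineral dust raised when sand is handled at gas wells, and 1 mg/m3 diesel particles, for 6 hours on each of 4 days. Lungs were taken 1, 7 or 27 days after the exposure ended, with 8 air and 8 exposed animals at each time. Summed expected counts per library ran from 9445687 to 14400337, with a median of 12004528. At day 1 the exposed libraries held 5.41% more counts than the air libraries (exact permutation test, two-sided, p = 0.0364, and 0.109 adjusted over the 3 days). At days 7 and 27 the totals differed by -0.216% (exact permutation p = 0.966) and -1.09% (exact permutation p = 0.841).

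In 4 pairs of libraries the counts lay far closer together than in any other pair. Numbering the libraries of each group from 1 to 8 by animal number, they were libraries 1 and 4 of the exposed day 1 group, 1 and 4 of the air day 7 group, 3 and 6 of the exposed day 7 group and 3 and 6 of the air day 27 group. Their median squared count difference was 1.44 to 1.66 times counting noise, against at least 2.40 in the other 164 pairs of libraries within a group. The heart muscle myosin Myh6, which varied from 0.403 to 157 CPM over the 48 libraries, stood at 83.0 and 81.9 CPM in the exposed day 1 pair. The immunoglobulin light chain Igkc stood at 872 and 886 CPM in the air day 27 pair, the latter being the highest of the 48 libraries. The pairs differed by more than counting noise, which does not settle whether the libraries of a pair came from separate animals. All 48 libraries stayed in the main tests, as planned before the data were examined. Tests were repeated with the counts of a pair summed into 1 animal, and means with SD use the pair's average as 1 replicate, which gives n = 7 in those groups.

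The day 1 comparison asked what the exposure did to lung expression shortly after it ended. EdgeR called 4 genes lower and none higher. Rises were called by DESeq2 (23 higher, 19 lower), with all 48 libraries in one fit (9 higher, 5 lower) and with the log2 total count as a covariate (1 higher, 1 lower). Dll4, a Notch ligand of endothelial cells (ENSRNOG00000014011), was at 168 ± 19.6 CPM in air (SD, n = 8) and 124 ± 12.9 CPM in exposed lungs (SD, n = 7), a log2 fold change of -0.42 ± 0.072 (SE, edgeR adjusted p = 0.0435). Slc29a1, a nucleoside transporter (ENSRNOG00000019752), went from 292.65 ± 18.9 to 239 ± 16.6 CPM, with a log2 fold change of -0.30 ± 0.048 (edgeR adjusted p = 0.0429). Sh3bp5 had a log2 fold change of -0.27 ± 0.044 and the endocytic recycling protein Ehd4 one of -0.20 ± 0.035. All 8 exposed libraries lay below the air mean for each of the 4 genes, where the naming rule required at least 7.

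None of the 4 genes passed once the closest pair was summed (0 of 14372 genes tested, with edgeR adjusted p of 0.0877 to 0.0894 for these 4). In the fit of all 16 libraries 14314 genes were tested, and no called gene reached a 1.5-fold change. By edgeR's quasi-likelihood test 1241 had an unadjusted p under 0.05, against 716 expected by chance. Random divisions of the 16 libraries into 8 and 8 gave up to 2238. Leaving out 1 library gave 17 genes without exposed library 3 (13 higher, 4 lower), 7 without exposed library 8 (2 higher, 5 lower), 3 without air library 5, 2 without air library 8, 1 each without air library 6 and exposed libraries 5 and 6, and 0 without any of the others.

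Genes fixed in advance as markers of particle exposure did not pass at day 1. Lcn2, an iron-binding protein of innate defence, was at 85.8 ± 33.1 CPM in air (SD, n = 8) and 191 ± 106 CPM in exposed lungs (SD, n = 7). All 8 exposed libraries lay above the air mean, with a log2 fold change of 1.34 ± 0.34 (edgeR adjusted p = 0.318). The highest exposed values, 407 and 394 CPM, were those of the closest pair, and the lowest, 86.0 CPM, lay barely above the air mean. With the pair summed the log2 fold change was 1.16 (edgeR adjusted p = 0.545). Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, was at 22.0 ± 8.89 CPM in air and 10.6 ± 3.14 CPM in exposed lungs, with all 8 exposed libraries below the air mean (edgeR adjusted p = 0.253). The neutrophil chemokine Cxcl1 had a log2 fold change of 0.70 ± 0.24 (edgeR adjusted p = 0.414) and the haem-degrading enzyme Hmox1 one of 0.30 ± 0.095 (edgeR adjusted p = 0.398). Nqo1, Ccl2, Mmp12, Spp1, Timp1 and Col1a1 had edgeR adjusted p of 0.632 to 0.971.

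**Figure D1:**
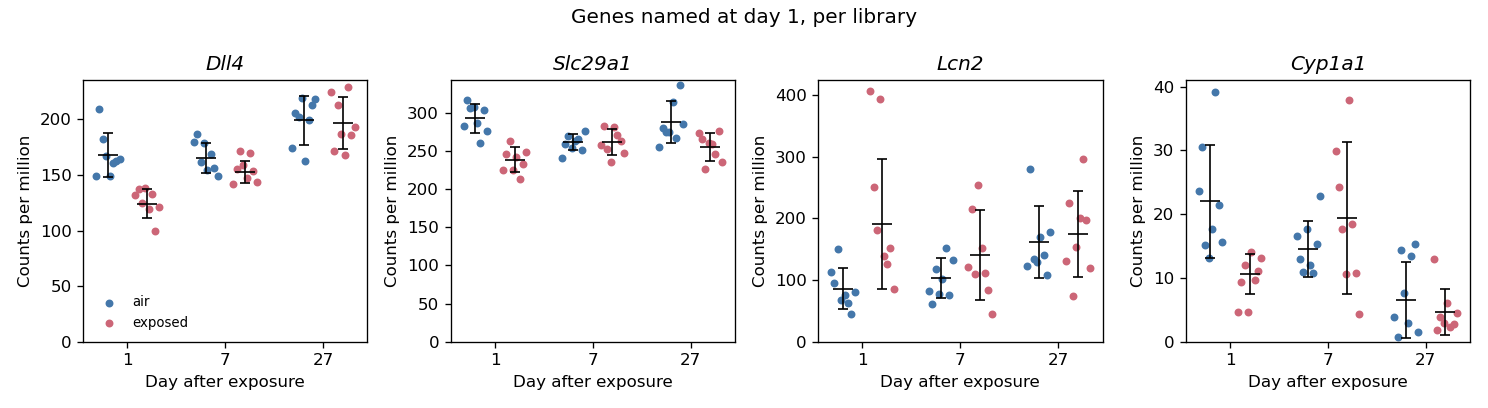
CPM (counts scaled to library size) of Dll4, Slc29a1, Lcn2 and Cyp1a1 (vertical axes) by day after exposure (horizontal axes), 1 point per library, air in blue and exposed in red, with bars for the mean and SD (a closest pair averaged as 1 replicate). At day 1 all 8 exposed libraries lie below the air mean for Dll4, Slc29a1 and Cyp1a1 and above it for Lcn2.

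Among the 32 gene lists fixed before the data were examined, 6 were called at day 1 by camera with a preset correlation of 0.01. Of 100 divisions of the 16 libraries, the real one included, 56 gave at least 6 called lists, so chance is not excluded. Secreted innate defence genes were shifted up, with a median log2 fold change of 0.15 over 12 members, and 3 of them (Lcn2, C3 and Pigr) were higher adjusted over the list alone, against 0 adjusted over all genes. Macrophage lysosome and lipid genes were shifted up (median 0.07 over 18 members), with Gpnmb, Ctsd and Lgals3 higher adjusted over the list alone. Heat shock and unfolded protein response genes were shifted up (median 0.08 over 15 members), with Sdf2l1 higher adjusted over the list alone. Endothelial genes were shifted down (median -0.08, 11 of 13 members below 0), as were interferon-stimulated genes (median -0.09, 18 of 18 below 0) and immediate early genes (median -0.15, 14 of 15 below 0), with 0 members of each passing adjusted over the list alone. With an estimated correlation none of the 6 was called, the camera adjusted p being 0.413 for innate defence, 0.246 for endothelial, 0.654 for immediate early and 0.720 for the remaining lists. With the closest pair summed and the preset correlation 5 lists were called. Innate defence (camera adjusted p = 0.0773) and interferon-stimulated genes (0.242) were not among them. B and plasma cells, shifted down, were (0.0189). With the closest pair averaged, mean list levels per library differed by 0.21 on the log2 scale for innate defence, -0.14 for endothelial and 0.35 for heat shock genes. The exact permutation p adjusted over the lists was 0.0771 for each, and 0.0418 for each with 8 against 8 libraries. The heat shock level lay above that list's median fold change, and its member Hsp90aa1 was at 39.2 ± 31.9 CPM in air and 82.0 ± 42.6 CPM in exposed lungs (edgeR adjusted p = 0.709). Hsp90aa1 varied widely within groups, and how reads were assigned to its identifier was not tested.

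The day 7 comparison asked what was present at that time, and edgeR called 0 of 14259 genes. At an unadjusted p under 0.05 there were 1208 genes, against 713 expected by chance and up to 1749 in random divisions of the libraries. Limma-voom called 0 and DESeq2 called 18. Leaving out 1 library gave 11 genes without exposed library 5, 3 without air library 8, 1 without exposed library 1 and 0 without any of the others. The smallest edgeR adjusted p was 0.227, shared by genes that included the cytokine signalling inhibitor Socs2 (log2 fold change 0.38 ± 0.073) and the actin-severing protein Gsn (log2 fold change -0.21 ± 0.045), which were chosen after their values were seen. Lcn2 was at 103 ± 32.8 CPM in air and 140 ± 73.4 CPM in exposed lungs (SD, n = 7 each, edgeR adjusted p = 0.713). Cxcl1 was at 9.79 ± 1.88 and 13.0 ± 2.20 CPM (edgeR adjusted p = 0.404), and the other 8 marker genes had adjusted p of 0.674 to 0.982.

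At day 7, 8 lists were called with the preset correlation. At least 8 were called in 41 of 100 divisions, the real one included, so chance is not excluded. Cholesterol and fatty acid synthesis genes were shifted down (median log2 fold change -0.22, 16 of 18 members below 0), with 5 members, among them Fdps, Msmo1 and Dhcr7, lower adjusted over the list alone and 0 adjusted over all genes. Cell cycle genes were shifted down (median -0.19, 17 of 19 below 0, Top2a lower adjusted over the list alone). Surfactant and alveolar type 2 cell genes were shifted down (median -0.10, 11 of 12 below 0), as were alveolar macrophage markers (median -0.09 over 14 members, 4 of them, Olr1, Cidec, Mrc1 and Krt79, lower adjusted over the list alone) and immediate early genes (median -0.16 over 15 members). Glucocorticoid response genes were shifted up (median 0.41, 11 of 12 above 0, Zbtb16 and Klf9 higher adjusted over the list alone), as were interferon-stimulated genes (median 0.29, 17 of 18 above 0) and red blood cell genes (median 0.19, 8 of 8 above 0). With an estimated correlation none was called, the camera adjusted p being 0.573 for cholesterol synthesis, cell cycle, alveolar macrophage and glucocorticoid genes and 0.716 for the others. With the closest pairs summed 6 lists were called with the preset correlation, without interferon-stimulated genes (camera adjusted p = 0.0853) and red blood cells (0.125). EdgeR then called 0 genes, with 985 at an unadjusted p under 0.05.

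The day 27 comparison asked what was present at the latest time, and 783 of 14192 genes were called by edgeR, 310 higher and 473 lower in exposed lungs. The count was 57 with a surrogate variable, 474 without a filter on low counts, 1609 with DESeq2 and 2227 with all 48 libraries in one fit. The other alternatives fixed beforehand gave 791 to 967. Most changes were small, with a median absolute log2 fold change of 0.24, and 18 genes changed at least 1.5-fold (6 up, 12 down). With the closest pair of air libraries (3 and 6) summed, 31 genes passed (10 up, 21 down), with their counts averaged 5 passed, and 0 of either set changed at least 1.5-fold. Leaving out 1 library gave 1926 genes without air library 2 and 1508 without exposed library 2. It gave 69, 221, 23, 111 and 123 without air libraries 3, 5, 6, 7 and 8, and 147, 9, 450, 220, 92 and 46 without exposed libraries 1, 3, 5, 6, 7 and 8. Of genes changed at least 1.5-fold, it gave 35, 78 and 38 without air libraries 1, 2 and 4 and 52 without exposed library 2. It gave 0, 7, 0, 1 and 5 without air libraries 3, 5, 6, 7 and 8, and 8, 0, 3, 3 and 1 without exposed libraries 1, 3, 6, 7 and 8. At an unadjusted p under 0.05 all 16 libraries gave 3790 genes, against 710 expected by chance and up to 3586 in random divisions.

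The genes named next had a mean of at least 1 CPM, a symbol that is not a provisional name and at least 7 of 8 exposed libraries on the same side of the air mean. Outside these limits called genes reached an absolute log2 fold change of 2.14. Within them, the largest rises at day 27 included Zbtb16, a transcription factor induced by glucocorticoids, at 5.88 ± 1.77 CPM in air (SD, n = 7) and 24.7 ± 29.1 CPM in exposed lungs (SD, n = 8), with a log2 fold change of 2.06 ± 0.56. Without exposed library 4 the exposed mean of Zbtb16 was 15.2 CPM and the log2 fold change 1.36 (edgeR adjusted p = 0.0532). Chodl (0.64 ± 0.14), the noradrenaline transporter Slc6a2 (0.63 ± 0.16), Aox4 (0.57 ± 0.13), Moxd1 (0.55 ± 0.16), Shroom1 (0.50 ± 0.14), the matrix protease Adamts9 (0.49 ± 0.095) and the haemoglobin scavenger receptor Cd163 (0.49 ± 0.14) followed, as log2 fold change ± SE. The largest falls within the same limits were those of Slc25a22 (-1.06 ± 0.30), the sphingosine kinase Sphk1 (-0.97 ± 0.23), the basophil protease Mcpt8 (-0.89 ± 0.25), Dr1 (-0.87 ± 0.22), the B cell receptor component Cd79a (-0.80 ± 0.20), Fcrla (-0.71 ± 0.16), the lipid droplet protein Cidec (-0.68 ± 0.19) and Dctpp1 (-0.67 ± 0.19). Their edgeR adjusted p lay between 0.0208 and 0.0481. Dr1 is uncertain, because 2 identifiers carry that name and the counting could divide reads between them. Of the 27 called genes that the naming rule gave at day 27, 1 passed with the closest pair summed, the endoplasmic reticulum chaperone Hsp90b1 (edgeR adjusted p = 0.0476), and the others had adjusted p up to 0.0902.

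B and plasma cell genes were shifted down at day 27 (camera adjusted p = 0.00217), with all 12 measured members below 0 and a median log2 fold change of -0.64. The members moved together between libraries, with an estimated correlation of 0.63. Of 100 divisions, the real one included, 94 gave at least 2 called lists, the number called at day 27, so chance is not excluded. Cd79a went from 33.8 ± 12.2 CPM (SD, n = 7) to 21.0 ± 4.38 CPM (SD, n = 8) and Fcrla from 26.8 ± 7.75 to 17.3 ± 2.69 CPM. These 2 members fell adjusted over all genes and 9 fell adjusted over the list alone. The highest air values were those of the closest pair, 53.6 and 58.8 CPM for Cd79a against 22.1 to 44.3 CPM in the other 6 air libraries. For Fcrla they were 42.1 and 35.7 CPM against 19.7 to 34.1 CPM. Without air library 3 or 6 the edgeR adjusted p was 0.0750 or 0.0729 for Cd79a and 0.0610 or 0.0641 for Fcrla, and with the pair summed 0.0686 and 0.0590. Of the 16 fits without 1 library, Cd79a passed in 4 and Fcrla in 7. The lymphocyte homing receptor Ccr7, in the T cell list, also fell (log2 fold change -0.57 ± 0.15). No other immune cell list was called (camera adjusted p of 0.195 to 0.914), and they went both ways. Below 0 lay 8 of 9 mast cell genes (median -0.65), 12 of 14 T cell genes (median -0.19), 10 of 12 neutrophil markers (median -0.26) and 12 of 14 alveolar macrophage markers (median -0.07). The numbers were 10 of 18 for macrophage lysosome and lipid genes, 8 of 14 for class II and dendritic cells and 7 of 12 for NK cells. Monocyte and interstitial macrophage markers lay above 0 in 11 of 15 (median 0.09). Heat shock and unfolded protein response genes were shifted up (camera adjusted p = 0.00939, median 0.17, 13 of 15 above 0), and Hsp90b1 rose from 875 ± 59.3 to 1054 ± 74.8 CPM. With an estimated correlation the camera adjusted p was 0.968 for both lists. With the closest pair summed and the preset correlation it was 0.0107 and 0.0139. With the pair averaged, mean list levels differed by -0.38 for B and plasma cells (exact permutation p adjusted over the lists = 0.319, and 0.172 with 8 against 8 libraries). They differed by 0.52 for heat shock genes (exact permutation adjusted p = 0.137, and 0.0771 with 8 against 8 libraries). The latter lay above the median fold change, Hsp90aa1 being at 50.5 ± 54.0 CPM in air and 158 ± 79.4 CPM in exposed lungs (edgeR adjusted p = 0.155). The SD of Hsp90aa1 in air exceeded its mean, so this list level rests in part on a gene that varied strongly between libraries.

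Single members of other lists passed at day 27 where the list was not called. The endothelial genes Tie1 (log2 fold change -0.17 ± 0.040) and Plvap (-0.20 ± 0.048) fell, as did Apoe (-0.32 ± 0.076), the ciliated cell gene Tppp3 (-0.28 ± 0.074), the macrophage phosphatase Acp5 (-0.45 ± 0.12), the glutathione transferase Gstp1 (-0.27 ± 0.071), the class II invariant chain Cd74 (-0.22 ± 0.059), the lysozyme Lyz2 (-0.24 ± 0.065) and Pparg (-0.33 ± 0.093). Of the marker genes, Cxcl1 was at 16.8 ± 3.33 CPM in air and 20.9 ± 2.09 CPM in exposed lungs (edgeR adjusted p = 0.0542), and the other 9 had adjusted p of 0.123 to 0.806, Lcn2 being at 161 ± 58.5 and 175 ± 69.8 CPM.

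Ribosomal protein and respiratory chain genes, sets added after the data were examined, had median log2 fold changes below 0 at day 27. Of 65 measured cytosolic ribosomal protein genes, 35 fell and 0 rose (median log2 fold change -0.23), and of 68 nuclear-encoded respiratory chain genes 24 fell and 0 rose (median -0.21). With the closest pair summed 2 and 0 fell (medians -0.21 and -0.20), with it averaged 0 and 0. With a surrogate variable 7 and 3 fell (medians -0.12 and -0.10). With all 48 libraries in one fit 51 of 66 and 44 of 68 fell (medians -0.23 and -0.21). Leaving out 1 library gave 0 to 53 and 0 to 37. With an estimated correlation (0.80 and 0.52) the camera adjusted p was 0.146 for both sets. Of 13 mitochondrially encoded genes 1 fell and 0 rose (median 0.005, 8 of 13 above 0). Gene length and GC content were not analysed here. On the log2 scale the mean ribosomal protein level of exposed libraries was lower by 0.22 than that of air libraries (exact permutation test, two-sided, p = 0.00637). With the closest pair averaged it was lower by 0.20 (exact permutation p = 0.0107). With that level as a covariate, edgeR called 0 genes at an adjusted p under 0.05 and 847 had an unadjusted p under 0.05 (710 expected by chance). All 783 genes kept their sign, and their median absolute log2 fold change went from 0.24 (median SE 0.061) to 0.12 (median SE 0.063).

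**Figure D2:**
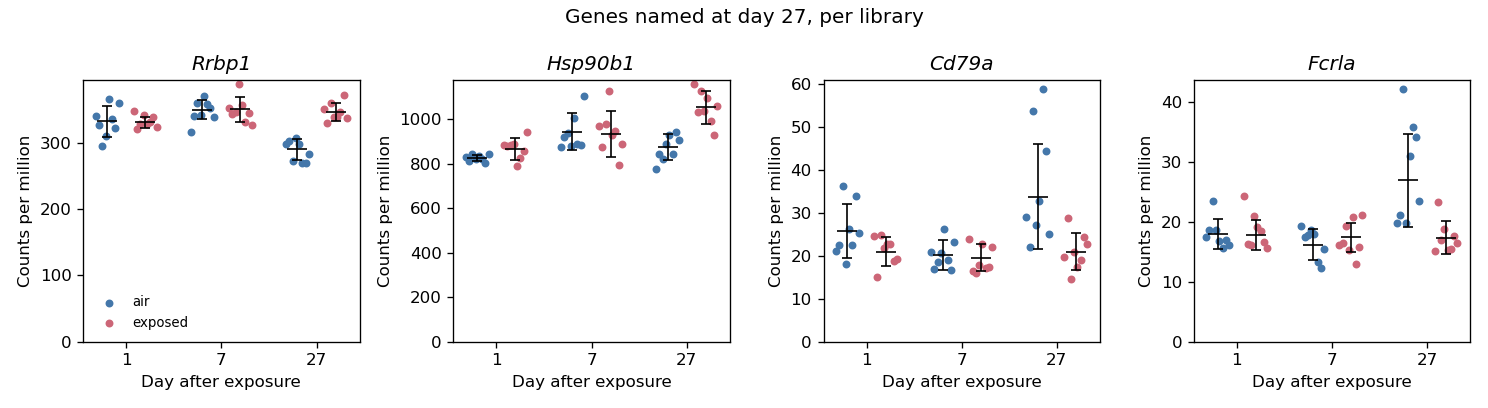
CPM (counts scaled to library size) of Rrbp1, Hsp90b1, Cd79a and Fcrla (vertical axes) by day after exposure (horizontal axes), 1 point per library, air in blue and exposed in red, with bars for the mean and SD (a closest pair averaged as 1 replicate). At day 27 all 8 exposed libraries lie above the air mean for Rrbp1 and Hsp90b1 and below it for Cd79a and Fcrla.

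**Figure D3:**
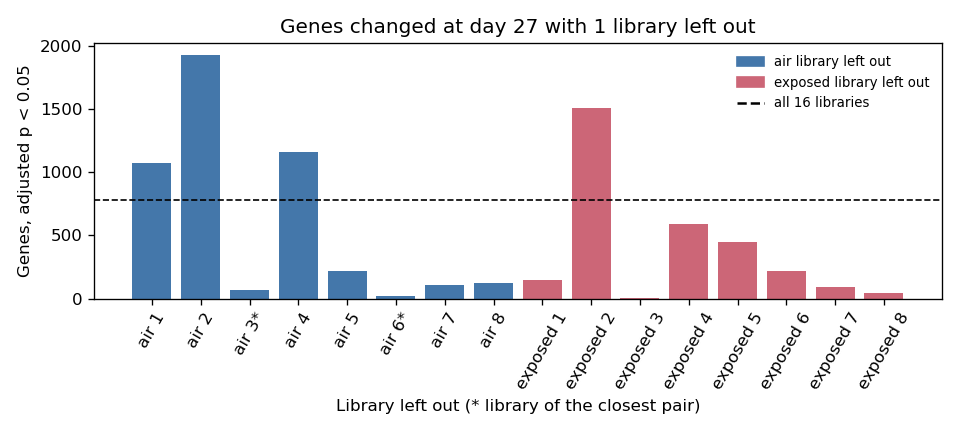
Number of genes called at day 27 (vertical axis) when the library on the horizontal axis was left out, with air libraries in blue, exposed libraries in red and the closest pair marked by asterisks. The dashed line is the count of 783 with all 16 libraries, and the bars run from 9 to 1926.

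Whether the exposure effect differed between days was tested with all 48 libraries in one fit of 14852 genes. Between days 1 and 7, 0 genes differed by edgeR, with 1114 at an unadjusted p under 0.05, 0 by limma-voom and 11 by DESeq2. Between days 1 and 27, 74 genes differed, 46 with a higher and 28 with a lower effect at day 27. Those with the smallest p were Ehd4 (difference of log2 fold changes 0.24 ± 0.039), the ubiquitin ligase Smurf2 (0.30 ± 0.051), the translation factor Eif5b (0.29 ± 0.053), the glycolytic enzyme Gapdh (-0.30 ± 0.057) and the splicing factor Luc7l2 (0.29 ± 0.055). Between days 7 and 27, 3 genes differed, among them Eif5b (0.27 ± 0.053) and the ribosome-binding protein Rrbp1 (0.26 ± 0.053). With the closest pairs summed, 9 genes differed between days 1 and 27, 0 between days 7 and 27 and 0 between days 1 and 7.

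No gene was called in the same direction at 2 days. None of the 4 genes lower at day 1 was among the 473 lower at day 27, where 0.134 would be expected of independent lists (Fisher's exact test, two-sided, p = 1). With so few genes called at days 1 and 7, the lack of overlap decides nothing about a shared response. Across genes, which are not independent replicates, the log2 fold changes of days 1 and 27 had a Pearson r of 0.20 and a Spearman rho of 0.29. Those of days 7 and 27 had an r of 0.12 and a rho of 0.19, and those of days 1 and 7 an r of 0.05 and a rho of 0.06.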

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

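The averaging of the closest pairs was chosen after the results were seen. A library stood apart from its group in 12 of 166 groups of values examined, where chance alone gives about 8.3. The gap of that library to its nearest neighbour, as a share of the group's range, was 0.584 for Dll4 in the exposed day 1 group, where library 7 was lowest. For Cyp1a1 in the same group the averaged pair of libraries 1 and 4 was lowest, with a gap of 0.624. For Col1a1 it was also lowest, with a gap of 0.581. Nqo1 in the air day 1 group had a gap of 0.596, with library 3 highest. Col1a1 in the exposed day 7 group had a gap of 0.579, with library 2 lowest. At day 27 the gaps were 0.542 for Sphk1 (exposed library 4, lowest) and 0.565 for Plvap (exposed library 1, highest). They were 0.582 for Cidec in air (library 2, lowest) and 0.533 for Cidec in exposed lungs (library 1, highest). Of list levels, the endothelial list in the exposed day 1 group had a gap of 0.645 (library 5, lowest), the heat shock and unfolded protein response list in the air day 1 group one of 0.612 (library 3, lowest) and the glucocorticoid response list in the air day 7 group one of 0.581 (library 8, highest).

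The exposure effect differed between days 1 and 27 for 74 genes and between days 7 and 27 for 3 genes by the edgeR test of the difference. Between days 1 and 27 the difference of log2 fold changes was 0.24 for Ehd4, 0.30 for Smurf2, 0.29 for Eif5b, -0.30 for Gapdh and 0.29 for Luc7l2. Between days 7 and 27 it was 0.27 for Eif5b and 0.26 for Rrbp1. Of 100 sets of exposure labels drawn within each day, the real one included, 6 gave at least 74 genes for days 1 and 27, so chance is not excluded for that count. The highest other set gave 1756 genes, which points to a structure among the libraries. What it consists of was not examined. For days 7 and 27 the libraries of a pair counted as separate animals. Of the 100 sets, 3 gave at least 3 genes, and the highest other gave 12. Chance is less likely for that count but not excluded, since the share was not adjusted over the counts examined. With the closest pairs summed, or without a filter on low counts, 0 genes differed between days 7 and 27. For days 1 and 7 the real count was 0, which all 100 reach, so that count decides nothing about chance. The highest other gave 18.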

How the results depend on the processing

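The alternatives that sum, average or drop a library of the closest pair, use the ribosomal protein level or leave out each library were chosen after seeing the data. Genes changed at day 1 numbered 4. They were 2 without a filter on low counts, 42 with DESeq2 (13 at least 1.5-fold against 0), 14 with all 48 libraries in one fit (3 at least 1.5-fold), 1 with a surrogate variable, 2 with the total count and 2 with the ribosomal protein level as covariate, and 0 with the closest pair summed, averaged or reduced to 1 library. Leaving out each library gave 0 to 17, the latter without exposed library 3, and 0 to 5 at least 1.5-fold. Genes changed at day 7 numbered 0, against 18 with DESeq2 (1 at least 1.5-fold), 1 with all 48 libraries (1 at least 1.5-fold) and 0 to 11 with a library left out (0 to 1 at least 1.5-fold), the latter without exposed library 5. Genes changed at day 27 numbered 783. They were 474 without a filter, 1609 with DESeq2, 2227 with all 48 libraries and 57 with a surrogate variable. They were 31 with the closest pair summed, 5 with it averaged, 23 with its second library left out, 0 with the ribosomal protein level, and 9 to 1926 with a library left out, without exposed library 3 and air library 2. Those changed at least 1.5-fold numbered 18 at day 27, against 33 with DESeq2, 69 with all 48 libraries, and 0 with a surrogate variable, the 3 pair settings or the ribosomal protein level, and 0 to 78 with a library left out.

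Genes whose effect differed between days 1 and 7 numbered 0, and 11 with DESeq2. Between days 1 and 27 they numbered 74, against 14 without a filter, 326 with DESeq2 and 9 with the closest pairs summed. Between days 7 and 27 they numbered 3, against 0 without a filter, 77 with DESeq2 and 0 with the closest pairs summed. The overlap of days 1 and 27 was 0 genes, and 1 at an adjusted p under 0.1. With an estimated correlation 0 lists were called at each day, with the pair summed or not. RLE factors, a mean of at least 1 CPM and limma-voom gave counts of changed genes at each day within 1.5 times. Of 1088 values of named genes under the alternatives fixed beforehand, 949 kept direction and side of the threshold, 63 no longer passed, 70 newly passed and 6 turned sign. Of 544 under those added later, the numbers were 389, 139, 0 and 16, leaving out single libraries aside. Most of these values belong to genes that had not passed in the main tests, for which keeping that side was likely beforehand. The 949 and 389 are therefore no measure of how well calls held. Of the 27 called genes named at day 27, between 1 (without air library 6 or exposed library 3) and 27 (without air library 2) passed with a library left out.

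The log2 fold changes that turned sign were these. At day 1 they were Spp1 (0.098 with limma-voom, 0.45 with a surrogate variable, 0.097 with the ribosomal protein level), Timp1 (0.035 with a surrogate variable, 0.00091 pair summed, 0.0031 averaged, 0.014 reduced, 0.011 with the ribosomal protein level) and Col1a1 (0.0012 summed, 0.0015 averaged). At day 7 they were Tnnt3 (0.00069 with DESeq2) and Col1a1 (-0.014 summed, -0.014 averaged, -0.014 reduced). At day 27 they were Mmp12 (-0.026) and Col1a1 (0.0031) with a surrogate variable, and, with the ribosomal protein level, Cd22 (0.015), Blk (0.0075), Cyp1a1 (0.76), Lcn2 (-0.044), Mmp12 (-0.11) and Timp1 (0.017). None of these had passed adjusted over all genes, while Cd22, Blk and Tnnt3 had passed adjusted over a list alone. The cause of these changes was not tested, except that fewer animals enter when a pair is merged or a library left out. Depth limits genes near 1 CPM, where a library of 9445687 counts holds few reads.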

Other observations

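The tests of shared cages and of library depth, and the fits that sum the closest pair, use the ribosomal protein level or leave out a library, were chosen after the results were seen.

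At day 1 several genes outside the marker genes had small p without passing, and were chosen after their values were seen. The chemokine Ccl6 had a log2 fold change of 0.73 ± 0.13 (SE), above the air mean in 7 of 8 exposed libraries (edgeR adjusted p = 0.134). The complement component Hc (log2 fold change 0.48 ± 0.099) and the macrophage pore-forming protein Mpeg1 (0.40 ± 0.083) were above the air mean in 8 of 8 exposed libraries (edgeR adjusted p = 0.147 for both). The club cell protein Scgb1a1 was at 6606 ± 1100 CPM in air (SD, n = 8) and 5097 ± 472 CPM in exposed lungs (SD, n = 7, a pair averaged), below the air mean in 8 of 8 libraries (edgeR adjusted p = 0.226). At day 7 the skeletal muscle genes Myh1 (31.8 ± 78.7 CPM in air against 1.12 ± 0.55 CPM in exposed lungs, edgeR adjusted p = 0.463) and Acta1 (21.6 ± 52.2 against 1.54 ± 0.64 CPM, edgeR adjusted p = 0.479) had an SD above the mean in air.

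In the 4 closest pairs of libraries the animal numbers differed by 3 each time. A candidate explanation is that both libraries of a pair came from the same RNA, for which the 500 genes most variable between the other libraries should have stayed under 2 times counting noise. The pairs lay between 2.36 and 3.02, above that bound but far below the other 164 pairs within a group. Those lay at 10.002 or more with a median of 18.3. By this test the same RNA and 2 similar lungs cannot be told apart. The bound left room for counting noise alone, so values above it do not argue against the same RNA. Animals sharing a cage stay open as well, since the 4 pairs were known when the test was set and not every cage need give a close pair. No biological explanation was tested.

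Of 100 divisions of the libraries, only the real one reached the 783 genes called at day 27 or the 18 changed at least 1.5-fold. The highest other gave 1 in both cases, which argues against chance for both counts with the libraries of the pair as separate animals. At an unadjusted p under 0.05, however, the real division gave 3790 genes and the highest other 3586. By that measure another division moved nearly as many genes. With the pair summed, 2 of 100 reached the 31 genes, and the highest other gave 299. The real division then had 3272 genes at an unadjusted p under 0.05, and the highest other 4202. The shares of divisions were not adjusted over the counts examined, so with the pair summed chance is less likely for the 31 genes but not excluded. Changes of at least 1.5-fold then number 0, which decides nothing about chance. The 299 genes point to a structure among the libraries that was not examined. Library depth is argued against, because the totals of the groups differed by -1.09% at day 27 (exact permutation p = 0.841). With the log2 total count as a covariate 967 genes passed. That adds little, since a covariate so alike in both groups could hardly have removed the calls. A candidate explanation for part of the count is 1 animal counted 2 times among the air libraries, since 0 of the other 6 air libraries left as few genes as either library of the pair (69 and 23), but 9 genes were left without exposed library 3 and 46 without exposed library 8, which belong to no pair. Another is an axis of variation that libraries also follow within groups, for which the Pearson r across 14127 genes, which are not independent replicates, between the within-group slope on ribosomal protein level at days 1 and 7 and the day 27 log2 fold change was -0.37 (Spearman rho -0.50, and r -0.35 from day 1 and -0.15 from day 7 alone), between the bounds of -0.5 and -0.2, with 683 of 748 called genes opposite in sign to the slope, so the axis and the exposure cannot be told apart. With the ribosomal protein level as a covariate, which itself differed between the groups, the median absolute log2 fold change of the 783 genes went from 0.24 (median SE 0.061) to 0.12 (median SE 0.063) with 783 of the same sign and 756 smaller, 534 having a larger SE, and 0 genes passed, so an effect of the inhaled mixture stays open.

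At day 1 the libraries of the closest pair counted as separate animals in the divisions. Of 100 divisions, 2 gave at least 4 genes, and the highest other gave 21. Chance is less likely for that count but not excluded, since the share was not adjusted over the counts examined. With the pair summed, averaged or reduced to 1 library 0 genes passed at day 1. For changes of at least 1.5-fold at day 1 the real count was 0, which all 100 reach, with a highest other of 19. At day 7 both real counts were 0, which all 100 reach, the highest others giving 7 genes and 0 genes changed at least 1.5-fold. These counts of 0 decide nothing about chance. For the lists called with the preset correlation chance is not excluded, with 56 of 100 divisions reaching the 6 of day 1 (highest other 18), 41 the 8 of day 7 (highest other 14) and 94 the 2 of day 27 (highest other 13).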
